A study of Mus musculus with 6 samples.

How the data were processed

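The 6 samples were primary bone marrow-derived macrophages of wild-type mice, treated for 12 h with 5 µM of a control peptide or 5 µM of RI-BPI, with 3 arrays per peptide. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns with DNase I, checked for quality, and made into biotin-labelled cRNA with an Ambion MessageAmp kit for Illumina bead arrays. The labels call the 3 arrays of a peptide technical replicates, and do not say whether they read 1 RNA. All p-values therefore measure the spread between arrays, and the variation between cultures or animals was not estimated.

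The authors deposited a table of mean bead intensity per probe and array, which per the file headers was not normalized and whose lowest values near the level of undetected probes show no background subtraction. Per the file headers the same deposited table holds a detection p-value for each probe and array, which moved in 936 even steps, the standard error of the bead intensities, and the number of beads, whose median was 45 on every array. GenomeStudio is named in the submitters' processing notes, without a version. A second table deposited by the authors holds normalized intensity values on a linear scale. Its column medians were all 46.33, each column followed the signals of its own array with r of at least 0.9995 across probes, and the method behind it is not given in the sources used here. It was used only as an alternative. No genome build was given in the sources used here, and no coordinates are printed.

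Probes were named through the platform annotation. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none. The Entrez identifiers of 34807 probes were found in a RefSeq table of the assembly GRCm38.p6, used for names only, and 0 symbols changed. The named probes covered 19057 genes. Ncor1 had no probe named here.

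Background was corrected with the normexp model of limma (version 3.58.1 in R version 4.3.3), with the background inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. Probes were kept if the detection p-value was under 0.01 on at least 3 of the 6 arrays, which left 13975 probes. A gene was represented by the kept probe with the highest mean log2 value over the 6 arrays, which gave 8205 genes. For other kept probes of a named gene a value is given where the log2 change differs from that of the used probe by at least 1.5 times or in sign, a limit set after the values were seen. The offset and the background estimate pull the changes of dim probes towards 0, so fold changes from a dim level are smaller on this scale than on a scale with full background subtraction.

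RI-BPI was compared with control using lmFit and eBayes of limma, a moderated two-sided test with 4 residual degrees of freedom per gene before moderation. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all 8205 genes. Counts are also given for changes of at least 1.5-fold. Errors of log2 changes are standard errors of the fit, with n = 3 arrays per group. Where a group was undetected on all 3 of its arrays, the change is given as "at least N-fold", for other probes of a gene too: the mean of the detected group against the mean, over arrays of the other group, of the higher of the probe's own value and the lowest value among detected probes.

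Before the data were examined, 27 gene lists were written from general knowledge of mouse genes: chemokines and cytokines, NF-kB pathway, LPS-induced genes, interferon response, reported Bcl6 targets, Bcl6 and corepressor complexes, cholesterol synthesis, LXR targets, PPAR targets and fatty acid oxidation, alternative activation, matrix and protease genes, S phase and mitosis, p53 response, ER stress and amino acid response, NRF2 and oxidative stress, heat shock, hypoxia and glycolysis, immediate early genes, macrophage identity, lysosome and autophagy, ribosomal proteins, and markers of neutrophils and granulocyte precursors, dendritic cells, lymphocytes, fibroblasts and stroma, erythroid, mast cells and basophils, and osteoclasts. The 24 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. An estimated correlation and fry served as alternatives. With an estimated correlation, camera takes its p-values from a t distribution with the 4 residual degrees of freedom. At a preset correlation the degrees of freedom follow the number of genes.

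The rule for named genes was also fixed then. It takes Bcl6, Ncor1 and a further gene that is not reported here; the 6 largest increases and 6 largest decreases among called genes whose groups do not overlap, leaving out predicted or clone-based names; up to 3 called increases and up to 2 called decreases in each of the lists on inflammation, interferon and Bcl6; up to 2 called members with the largest absolute change in every other list; and the largest member of a list without a called member.

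Other settings tried were no background correction, normexp without detection p-values, median centring, cyclic loess, the submitters' processed values, no filter, detection on all 6 arrays, every probe as its own row, the mean of a gene's probes, a trended and robust variance model, a test against a minimum change of 1.2-fold, the replicate number as a block, and leaving out each array. Neither a chip identifier nor a batch is given in the sources used here, so a fit with the chip as a block was not run. All 6 per-array column sets were used.

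The analysis was tested on simulated data for the comparison of RI-BPI with control, 3 arrays against 3, with real probe means and either of 2 noise models. The first noise model tried was the raw spread of the control arrays, which also holds differences in scale between arrays. It missed the recovery that had been required at 2-fold, after which a model with the bead error, scaled to about the spread between arrays, was added and the requirement was lowered to hold for both. With the raw spread, 80% of 60 genes changed 2-fold were recovered with the right sign, 39.7% of 68 changed 1.5-fold and 2.90% of 69 changed 1.2-fold, with 5 false calls among 8232 unchanged genes of 8449 tested. With the bead error, the shares were 100% of 60, 66.2% of 68 and 2.86% of 70, with 5 false calls among 8210 of 8428. The median size recovered for a 2-fold change was 0.91 on the log2 scale under both. A planted list raised 1.3-fold had a camera p of 1.31e-15 and 5.25e-18, and 2% and 1% of random lists had a p under 0.05. Beside the planted list, only 197 and 198 of the tested genes were changed, against 61.3% of genes called in the data. The noise was drawn for each probe on its own, without correlation between genes. So the shares recovered and the list p-values describe the simulated setting and not the real fit.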

Results

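Macrophages grown from mouse bone marrow were profiled on Illumina bead arrays after 12 h with 5 µM RI-BPI or 5 µM control peptide, 3 arrays each. RI-BPI is a retro-inverso peptide built to keep the transcriptional repressor Bcl6 from binding corepressors. The comparison asks which transcripts change with this peptide, and the arrays do not show whether that contact was blocked. Median intensities per array lay between 45.8 and 47.4. Of 45281 probes, 13866 to 14357 were detected per control array and fewer, 12931 to 13843, per RI-BPI array. The cause of this difference was not tested. Arrays of the same peptide correlated across genes at r = 0.992 to 0.996, and arrays of different peptides at 0.945 to 0.948. The spread between arrays was 1.12 times the bead error with control peptide and 1.28 times with RI-BPI, so the replicates differed by little more than the error of the beads. The labels call the 3 arrays per group technical replicates, and whether they are repeat hybridisations of 1 RNA is not stated. The limit is then the number of cultures per peptide, which can be 1, and the variation between cultures was not estimated.

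Most of the measured genes differed between the peptides, in both directions. The lists called up with camera were NF-kB pathway, LPS-induced and immediate early genes, oxidative stress, and ER stress with amino acid response, of which 9 of 29 members fell. Those called down were S phase and mitosis, cholesterol synthesis, interferon response and macrophage identity. With an estimated correlation only S phase and mitosis (adjusted p = 0.0404) and interferon response (0.0444) held, against 0.0841 for ER stress and 0.059 for the other lists called. The largest increase was in Prf1, which encodes the pore-forming protein perforin, by 7.10 ± 0.10 on the log2 scale (137-fold). The largest decrease was in Ccnd1, the gene of cyclin D1, which fell by 4.29 ± 0.11 (19.6-fold lower). Of 8205 genes, 2518 were higher and 2513 lower, together 61.3%, and the median change over all genes was 0.008. Quantile normalization gives every array the same distribution, so this balance is largely set by the scaling. With median centring 1988 genes were higher and 2807 lower, and the median was -0.08. With a change of at least 1.5-fold the counts were 1212 higher and 1244 lower, and 65 rose and 30 fell by at least 4-fold. The 1.5-fold counts depended on the background: without its correction they were 763 and 786. Signals of RNAs without a poly(A) tail, named after their values were seen, also differed, and all 4 measured were higher. Whether the level of these RNAs in the cells or the amount entering the label differed cannot be told apart here. The small nuclear RNA Rnu6 was higher by 3.77 ± 0.11 and 28S ribosomal RNA, Rn28s1, undetected in control, at least 3.48-fold. The small nucleolar RNAs Snora65 and Snora70 were higher by 1.25 ± 0.12 and 0.41 ± 0.12.

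**Figure D1:**
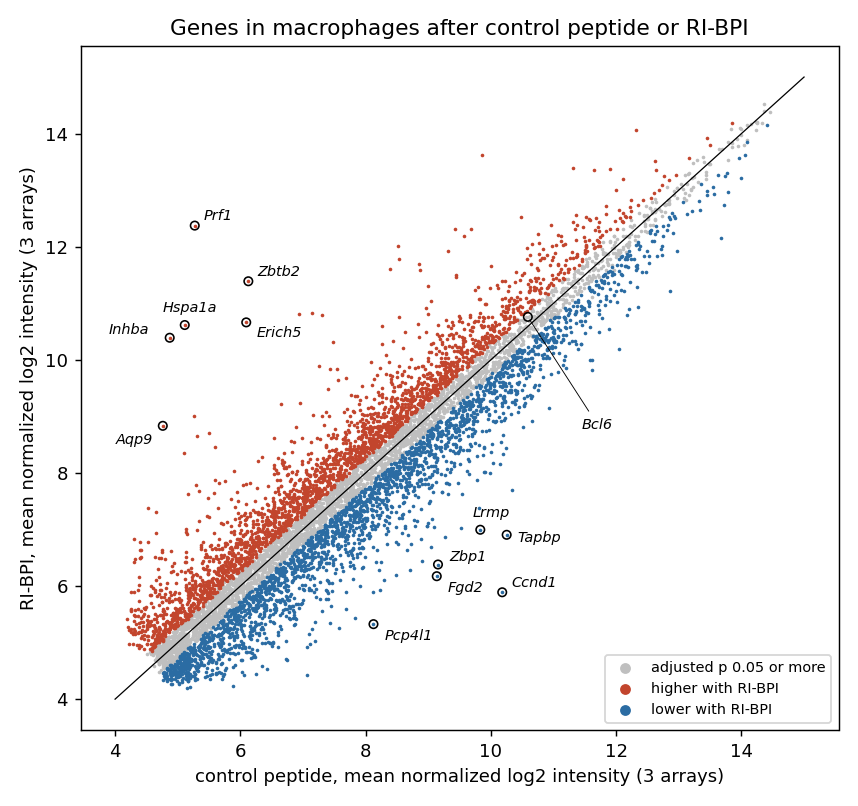
Mean normalized log2 intensity of each of 8205 genes with control peptide (x axis) and RI-BPI (y axis), 3 arrays each. Red points are the 2518 genes called higher with RI-BPI, blue points the 2513 called lower, grey points the rest, and circles mark Bcl6, which lies near the line of equal values, and the genes with the largest changes, led by Prf1 at 5.27 against 12.37.

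Bcl6 itself was measured at 10.59 ± 0.22 (SD, n = 3) with control and 10.76 ± 0.08 with RI-BPI, a difference of 0.17 ± 0.12 that did not pass the test (adjusted p = 0.226), and without control replicate 2 the difference was 0.04. Of 20 measured genes of Bcl6 and corepressor complexes, 7 rose, 5 fell and 8 were not called. Bcor, a corepressor that binds Bcl6, rose by 1.19 ± 0.12, the partner Zbtb17 (Miz-1) by 0.84 ± 0.11 and the histone deacetylase scaffold Sin3a by 0.68 ± 0.12. Kdm2b, a histone demethylase of a Bcor complex, fell by 0.70 ± 0.11 and the class II deacetylase Hdac7 by 0.54 ± 0.11. As a list these genes did not pass the test (camera adjusted p = 0.28). Genes reported elsewhere as Bcl6 targets moved both ways: of 30 measured, 11 rose and 12 fell, with a median of 0.009 and a camera adjusted p of 0.937. Gadd45a, a growth arrest and DNA damage gene, rose by 3.50 ± 0.14, the cytokine signalling inhibitor Cish by 1.37 ± 0.11 and Id2 by 1.34 ± 0.11, whereas Ccnd1 fell by 4.29 ± 0.11 and the oxysterol receptor Gpr183 by 1.32 ± 0.10. Another probe of Id2 gave 0.81.

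The other large increases came from low control levels. Inhba, which encodes the activin A subunit, rose by 5.52 ± 0.15 (45.8-fold) and was detected on 2 of 3 control arrays. The inducible heat shock gene Hspa1a rose by 5.50 ± 0.13 (45.3-fold). Its other probes, undetected in control, rose at least 15.5-fold and 1.45-fold, and since Hspa1a and Hspa1b are near-identical copies their signals cannot be assigned with certainty. The zinc finger gene Zbtb2 rose by 5.26 ± 0.12, Erich5 by 4.57 ± 0.15 and the glycerol channel Aqp9 by 4.07 ± 0.12, the last detected on 2 of 3 control arrays. Prf1, Erich5 and Aqp9 each had a further probe that was not detected on any array. Among the decreases, Tapbp, the tapasin gene of MHC class I peptide loading, fell by 3.35 ± 0.11 (10.2-fold lower) at the brighter probe, and its other probe gave -1.47. Fgd2, a Cdc42 exchange factor, fell by 2.96 ± 0.11, Lrmp by 2.84 ± 0.14, Pcp4l1 by 2.80 ± 0.11, and Zbp1, a sensor of Z-form nucleic acid, fell by 2.77 ± 0.11. Dimmer probes of Zbp1 and Lrmp fell less, with -0.47 at a probe of Zbp1 detected with both peptides. Another probe of Ccnd1 gave -4.34. Further probes, undetected with RI-BPI, fell at least 2.52-fold for Ccnd1, 1.29-fold for Zbp1 and 1.07-fold for Pcp4l1. Adjusted p-values of the used probes of these 12 genes ranged from 1.12e-20 for Prf1 to 3.22e-12 for Lrmp.

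Of 30 measured chemokines and cytokines, 14 rose, 10 fell and 6 were not called. Cxcl1 and Cxcl2, which attract neutrophils, rose by 3.69 ± 0.12 (12.9-fold) and 2.61 ± 0.11 (6.11-fold). Csf1, the macrophage growth factor, was undetected on the 3 control arrays and rose at least 4.22-fold. The monocyte chemokine Ccl12, detected on 1 of 3 RI-BPI arrays, was 2.83-fold lower, and Ccl6 fell by 1.16 ± 0.12. The list as a whole did not pass (camera adjusted p = 0.177), with a median of 0.12 and a mean of 0.40.

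Most NF-kB pathway genes rose: 22 of 33 measured members rose, 5 fell and 6 were not called, with a median of 0.53. The early response genes Ier3 and Gadd45b rose by 2.84 ± 0.12 and 2.34 ± 0.14 (1.55 at another probe of Gadd45b), and the subunit gene Rel by 1.82 ± 0.12. The kinase Ikbke fell by 1.27 ± 0.11 and the inhibitor Nfkbie by 0.93 ± 0.12. The list passed at a camera adjusted p of 0.00146, but not with an estimated correlation (adjusted p = 0.059). Of 35 measured LPS-induced genes, 19 rose, 6 fell and 10 were not called, with a median of 0.39. Beside Cxcl1 and Cxcl2, the interleukin 1 receptor antagonist Il1rn rose by 1.95 ± 0.11, with 0.92 at another probe. Marcksl1 fell by 1.53 ± 0.13 and the fatty acid receptor Gpr84 by 1.09 ± 0.12. This list passed at a camera adjusted p of 0.00342, but not with an estimated correlation (adjusted p = 0.059). Of the 35 LPS-induced genes, 21 also stood in another list, and 4 genes were in both this list and the NF-kB list.

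Interferon-responsive genes fell, although the gene of interferon beta rose. Of 41 measured members, 30 fell, 4 rose and 7 were not called, with a median of -0.61 and quartiles of -1.11 and -0.25. The nucleic acid sensor family gene Ifi205 fell by 1.91 ± 0.10, with -0.78 at another probe, and the antiviral GTPase Mx1 fell by 1.83 ± 0.14. Ifnb1 rose by 2.64 ± 0.11 (6.25-fold) and was detected on 1 of 3 control arrays. Irgm1 rose by 0.41 ± 0.10 at its brightest probe but another detected probe gave -0.67, so its direction is not settled. Oas1a rose by 0.33 ± 0.11 (adjusted p = 0.0161), a call lost without control replicate 1 (adjusted p = 0.0638), without RI-BPI replicate 3 (0.0746) and with median centring (0.155). As a list these genes had a camera adjusted p of 2.22e-06, and with an estimated correlation the adjusted p was 0.0444.

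Genes of DNA replication and mitosis fell together. Of 29 measured members of the S phase and mitosis list, 25 fell, 1 rose and 3 were not called, with a median of -1.08. Thymidine kinase Tk1 was undetected on the 3 RI-BPI arrays and fell at least 4.65-fold, and topoisomerase Top2a fell by 1.95 ± 0.10. The licensing factor Cdt1, named after its value was seen, was the member that rose, by 0.84 ± 0.12. The camera adjusted p was 8.09e-10, and with an estimated correlation the adjusted p was 0.0404. Cholesterol synthesis genes fell as well, 17 of 19 measured, with 1 higher, 1 not called and a median of -0.92. Hsd17b7 and Cyp51, enzymes of the later steps from lanosterol, had changes of -2.45 ± 0.12 (5.48-fold lower) and -2.43 ± 0.13 (5.37-fold lower). Insig2, which retains SREBP in the ER and was named after its value was seen, rose by 0.37 ± 0.12. Camera gave the list an adjusted p of 1.65e-07, and the adjusted p was 0.059 with an estimated correlation. Of 12 measured LXR targets, 2 rose and 6 fell (camera adjusted p = 0.174). The sterol exporter Abcg1 rose by 1.23 ± 0.11 and Pltp, undetected with RI-BPI, fell at least 1.79-fold. With undetected members at their bound, the LXR median moved from -0.39 to -0.19. Of 16 genes of PPAR targets and fatty acid oxidation, 3 rose and 9 fell (camera adjusted p = 0.177), with the lipoprotein lipase gene Lpl at -1.51 ± 0.10 and the thiolase Acaa2 at -1.49 ± 0.11, with -0.96 and -1.16 at other probes.

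The list of NRF2 and oxidative stress rose, and that of ER stress and amino acid response split. In the list of ER stress and amino acid response, 17 of 29 measured members rose, 9 fell and 3 were not called. The ATF4 target Trib3 rose by 3.87 ± 0.11 (14.6-fold), with 2.44 at another probe, and Ppp1r15a (GADD34) by 3.25 ± 0.12 (9.51-fold). The members that fell, named after their values were seen, were chaperones and folding or degradation factors of the ER: Calr (-2.49), Sdf2l1 (-2.30), Hsp90b1 (-1.07), Pdia4, Creld2, Pdia6, Edem1, Hspa5 (-0.40) and Dnajc3. The camera adjusted p was 0.011, and the adjusted p was 0.0841 with an estimated correlation. In the list of NRF2 and oxidative stress, 13 of 20 rose and 1 fell, with a median of 0.60. The cystine transporter Slc7a11 rose by 2.31 ± 0.12, with 1.41 at another probe and at least 1.96-fold at a probe undetected in control, and heme oxygenase Hmox1 by 2.05 ± 0.11. This list passed at a camera adjusted p of 0.000435, and the adjusted p was 0.059 with an estimated correlation. Of 22 immediate early genes, 16 rose and 2 fell, with a median of 0.85, or 0.76 with undetected members at their bound. Klf4 rose by 2.87 ± 0.12 and Ier3, which is also in the NF-kB list, by 2.84 ± 0.12. For this list the camera adjusted p was 6.56e-05, and the adjusted p was 0.059 with an estimated correlation.

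Several other lists had members moving both ways. Of 13 heat shock genes, 7 rose and 2 fell. Hspa1a led them, and Hspa1b, undetected in control, rose at least 1.65-fold. The list did not pass (camera adjusted p = 0.0548), but did with median centring (0.0307) and with no filter (0.0222). With an estimated correlation its adjusted p was 0.184. Of 21 p53 response genes, 10 rose and 7 fell (camera adjusted p = 0.58), with a median of -0.07 and a mean of 0.19. Gadd45a rose and Sesn1 fell by 2.42 ± 0.11. Of 20 genes of hypoxia and glycolysis, 6 rose and 4 fell (camera adjusted p = 0.249), with Ndrg1 higher by 2.64 ± 0.11 and Vegfa by 1.41 ± 0.11. Of 29 genes of lysosome and autophagy, 4 rose, 5 fell and 20 were not called (camera adjusted p = 0.937). The cargo receptor Sqstm1 rose by 1.75 ± 0.11 and Gabarapl1 by 1.53 ± 0.11. The median of that list was -0.01 and its mean 0.05. Of 20 ribosomal protein genes, 17 were not called and the median was -0.03 (camera adjusted p = 0.632), or -0.15 with median centring, under which the median of all genes was -0.08. Rpl3 fell by 0.47 ± 0.11 and Rplp0 rose by 0.38 ± 0.11, the latter not called with median centring (adjusted p = 0.0503).

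**Figure D2:**
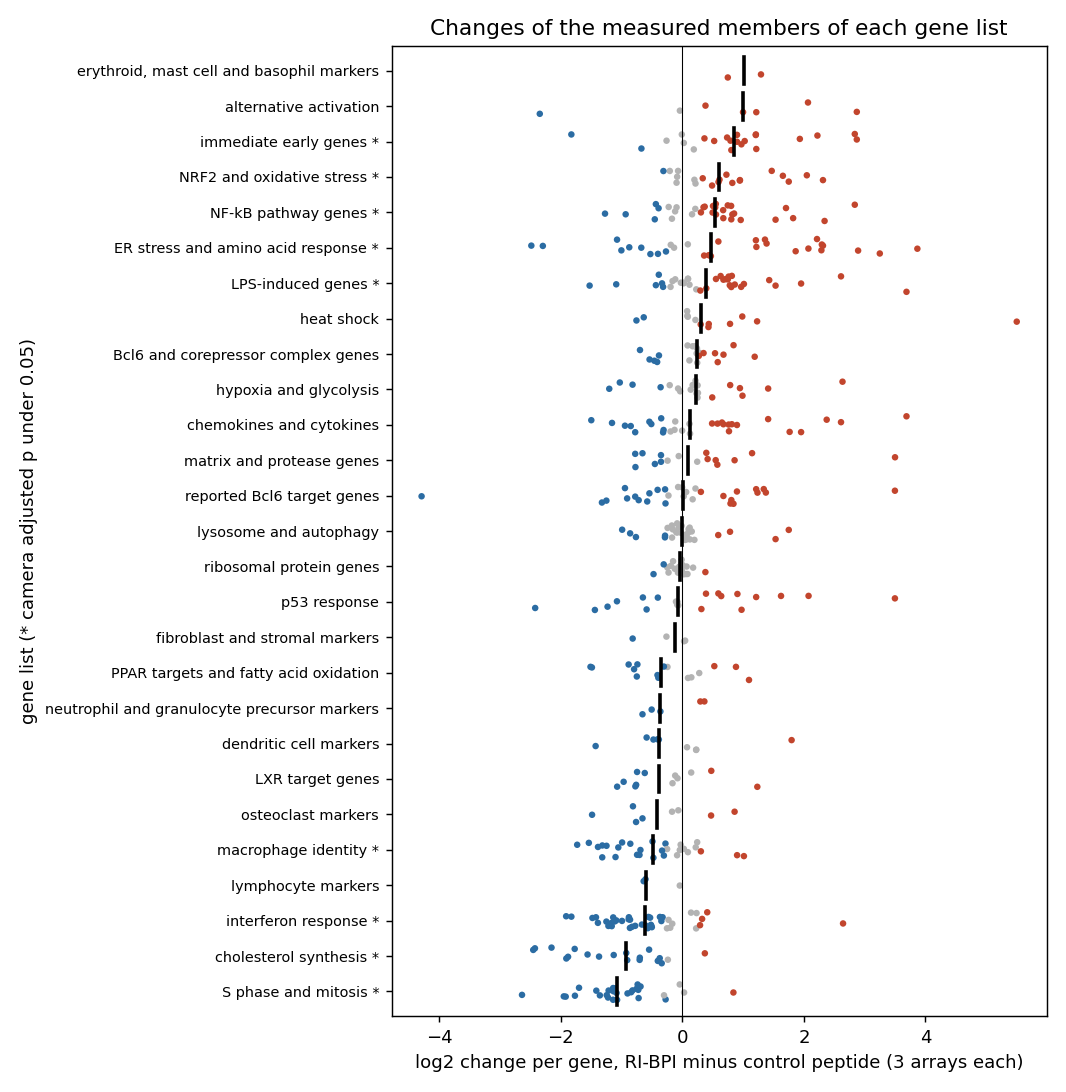
Log2 change (RI-BPI minus control peptide, x axis) of every measured gene of the 27 gene lists (y axis), ordered by median. Red points are genes called higher, blue points genes called lower and grey points genes not called, black bars are list medians, and asterisks mark lists with a camera adjusted p under 0.05. Medians run from -1.08 for S phase and mitosis to 1.02 for the erythroid, mast cell and basophil markers, of which only 2 genes were measured. With Kit, undetected in control, at its bound, that median is 0.80 and lies below the median of alternative activation.

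Surface and identity genes of macrophages fell more often than they rose. Of 29 measured, 18 fell, 3 rose and 8 were not called, with a median of -0.48. The high-affinity Fc receptor Fcgr1 fell by 1.73 ± 0.11 and sialoadhesin, Siglec1, by 1.54 ± 0.11. Csf1r (-0.09), Lyz2 (-0.04) and Cd14 (0.09), named after their values were seen, were not called. The camera adjusted p was 0.00146, and the adjusted p was 0.059 with an estimated correlation. Of 20 genes of alternative activation with a probe, 7 were measured, of which 5 rose and 1 fell (camera adjusted p = 0.0548). Arg1, Retnla and Cd163, named after their values were seen, were not detected on any array. Klf4 led the increases, and the mannose receptor Mrc1 fell by 2.35 ± 0.11 (5.08-fold lower). The list passed without control replicate 1 (adjusted p = 0.0316), without control replicate 2 (0.0364) and without RI-BPI replicate 3 (0.0297), and with median centring (0.0308). It did not pass without the other arrays, nor with an estimated correlation (adjusted p = 0.32). Of 16 matrix and protease genes, 7 rose and 6 fell (camera adjusted p = 0.615). Collagenase Mmp13 rose by 3.50 ± 0.11 (11.3-fold), with at least 2.10-fold at another probe undetected in control, and elastase Mmp12 by 1.15 ± 0.11.

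Markers of other cells that such cultures can hold were mostly below the detection filter, except those of osteoclasts. Of 24 genes of neutrophils and granulocyte precursors with a probe, 5 were measured, of which 2 rose and 3 fell (camera adjusted p = 0.58). Mmp9, at 1 of 3 RI-BPI arrays detected, fell by 0.66 ± 0.12, and Csf3r fell by 0.51 ± 0.11, with -0.43 at another probe. Of its probes undetected with RI-BPI, 1 fell at least 1.16-fold and the change of the other did not pass the test (adjusted p = 0.0644). Of 23 dendritic cell markers with a probe, 9 were measured, of which 1 rose and 5 fell (camera adjusted p = 0.513). The costimulator Cd86 rose by 1.80 ± 0.13 and H2-DMb1 fell by 1.43 ± 0.11. Of 22 lymphocyte markers with a probe, 3 were measured and 2 fell. Cd79b, undetected with RI-BPI, fell at least 1.15-fold, and Blnk fell by 0.61 ± 0.11. Of 24 fibroblast and stromal markers with a probe, 4 were measured and 1 fell, S100a4 by 0.82 ± 0.12. Of 20 erythroid, mast cell and basophil markers with a probe, 2 were measured. Kit, undetected in control, rose at least 1.80-fold, and the histamine enzyme Hdc rose by 0.75 ± 0.10. Of 15 osteoclast markers with a probe, 8 were measured, of which 2 rose and 4 fell (camera adjusted p = 0.264). The fusion receptor Dcstamp was at -1.49 ± 0.11 and cathepsin Ctsk at 0.86 ± 0.10.

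**Figure D3:**
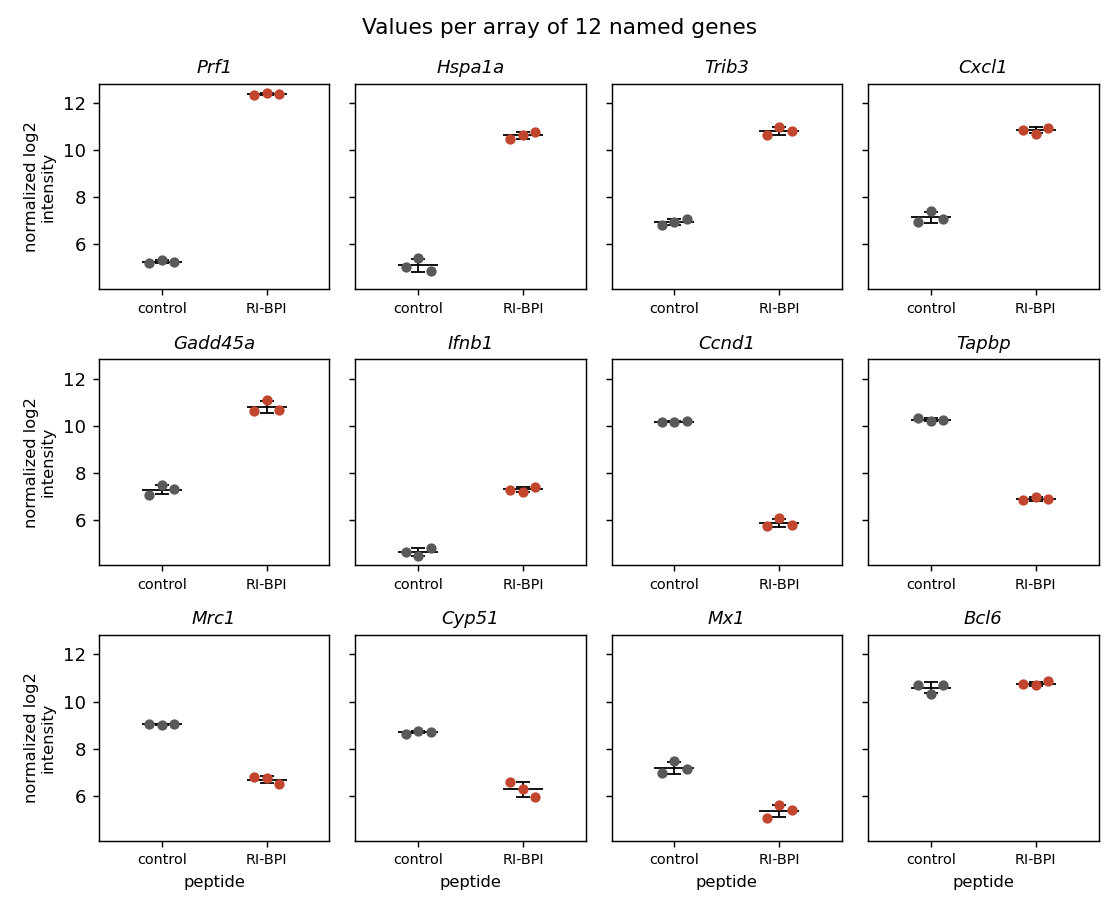
Normalized log2 intensity (y axis) on each of the 3 control peptide arrays (grey points) and 3 RI-BPI arrays (red points) for 12 named genes, with mean and SD as bars. Bcl6 overlaps between the peptides, and the other genes are separated by more than the spread between arrays.

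Across the 24 tested lists, 5 were called up and 4 down with camera. With an estimated correlation 2 of the 9 calls held, the interferon response and S phase and mitosis. That setting also uses only 4 residual degrees of freedom, so a lost call there does not show correlation between members. By fry, which does not set a list against other genes, 21 lists were called. Adjusted over the list alone, the counts of called genes were as over all genes except for interferon response (32 lower), Bcl6 and corepressor complexes (8 higher), PPAR targets (4 higher, 10 lower), matrix genes (7 lower), macrophage identity (4 higher, 19 lower), lysosome and autophagy (3 lower) and ribosomal proteins (1 lower).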

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

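Probes without a gene name here are not among the 8205 genes compared in the report, and among them signals also differed between the peptides. Of 1779 such probes that passed the detection filter, 516 were higher and 472 lower with RI-BPI in the limma fit. The largest increases were probe ILMN_1251193, at 7.21 with control and 11.54 with RI-BPI (log2 change 4.33 ± 0.11 SE, adjusted p = 3.67e-16, n = 3 arrays each), and probe ILMN_1227282, at 5.00 and 9.09 (4.08 ± 0.11, adjusted p = 5.26e-16). All 3 arrays of both peptides detected both probes. With 3 arrays per group, no array was tested as an outlier.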

How the results depend on the processing

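Of 876 values of the 77 named genes under the alternatives, 870 kept their side of the threshold and, where called, their direction. The same held for 284 of 309 list tests, and 62 of 70 gene counts stayed within 1.5 times. Every probe as its own row gave 4060 higher and 4256 lower (1889 and 2116 by at least 1.5-fold) because it tested 13975 probes. Without background correction the 1.5-fold counts were 763 and 786: of genes past 1.5-fold in the main setting, 204 of 748 stayed past it among the 2735 dimmest genes and 729 of 795 among the 2735 brightest. Testing against a minimum of 1.2-fold gave 1402 and 1425, a stricter null. Calls shared with the main setting, all of the same sign, were 4696 of 4863 without background correction, 4487 of 4795 with median centring, 4932 of 5027 with cyclic loess and 4846 of 4994 with the submitters' values. Median centring put 41.5% of calls on the higher side against 50% in the main setting. Without any 1 array, 2258 to 2389 genes were higher and 2094 to 2484 lower.

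With an estimated correlation, adjusted p rose to 0.059 for NF-kB, LPS-induced, cholesterol, NRF2, immediate early and macrophage identity lists and 0.0841 for ER stress. Of these lists, only cholesterol had an estimated correlation (0.0467) above the preset 0.01. The rest ran from -0.0346 for immediate early genes to 0.00371 for macrophage identity, so stronger correlation between members did not raise their p-values. This setting takes p-values from 4 residual degrees of freedom, which makes them larger at the same statistic. Fry, which sets no list against other genes, also called chemokines (7.29e-05), Bcl6 and corepressors (0.00395), LXR (0.0039), PPAR (0.000157), alternative activation (0.00146), matrix (0.00437), p53 (0.0061), heat shock (8.18e-05), hypoxia (0.00146), ribosomal (0.00863), neutrophil (0.00567) and osteoclast (0.000456) lists. Alternative activation passed with median centring (0.0308), and without any 1 array its adjusted p ran from 0.0297 to 0.22. Heat shock passed with median centring (0.0307) and with no filter (0.0222). The other probe of Irgm1 reversed its change to -0.67, and a probe of Csf3r did not pass (0.0644). For the results of this paragraph the cause was otherwise not tested. The chip as a block was not run, as no chip is given. The replicate numbers did not pair arrays: same-numbered arrays deviated together at r = 0.02, 0.002 and 0.03, and not every array correlated best with its own number. With the replicate block 2533 genes were higher and 2527 lower, and no call of a list or named gene changed. Signal over background limits dim genes: among those 748 dim genes the log2 change without correction was 0.524 times the main one (median).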

Other observations

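The lists and tests of this part were chosen after the data were seen, apart from the tests on other splits of the arrays. The p-values of lists chosen this way give no valid error rate and describe the lists only. Genes of aminoacyl-tRNA synthetases rose, 13 of 18 measured, with 2 lower and a median of 0.66 (camera adjusted p = 0.00132, 9 lists tested; adjusted p = 0.0333 with an estimated correlation). Sars rose from 8.19 to 9.73 and Aars from 9.79 to 11.29 on the log2 scale. Of 13 measured circadian clock genes 10 rose and 1 fell, with a median of 1.08 (adjusted p = 3.91e-05; 0.0297 with an estimated correlation). Among them the repressor Bhlhe40 rose from 7.48 to 10.31, Nr1d1 from 4.76 to 6.61 and Arntl (BMAL1) from 5.69 to 7.12, while the output gene Dbp fell from 8.22 to 7.38. Of 28 constitutive proteasome genes 15 rose and 0 fell, with a median of 0.32 (adjusted p = 0.00324; 0.0333 with an estimated correlation).

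Antigen presentation genes fell in both classes. Of 16 genes of MHC class I and peptide loading 13 fell and 0 rose, with a median of -0.59 (camera adjusted p = 3.32e-05, or 0.0297 with an estimated correlation). Calr went from 9.52 to 7.03 and Pdia3 from 11.21 to 9.86. B2m stood at 13.93 and 13.91 and was not called, nor were H2-D1 and Tap1. Calr is also in the ER stress list, and Psmb8, Psmb9 and Tap1 are in the interferon list, so these genes are not separate from those lists. Of 12 MHC class II and processing genes 11 fell and 0 rose (median -0.46, adjusted p = 0.000412; 0.0333 with an estimated correlation), with H2-DMa from 9.32 to 7.63. Of 8 Toll-like receptor genes 6 fell, led by Tlr8 from 7.58 to 5.26, and 2 rose, among them Tlr2 from 11.51 to 12.53. That list passed at an adjusted p of 0.0353, and did not pass with an estimated correlation (adjusted p = 0.36), without RI-BPI replicate 1 (0.0653) or with median centring (0.0557). Of 75 oxidative phosphorylation genes 28 fell and 2 rose (median -0.17, adjusted p = 0.011; 0.0333 with an estimated correlation). The medians of these lists kept their sign under 4 other scalings and without each array.

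Replication-dependent histone genes, whose messenger RNAs normally end in a stem-loop without a poly(A) tail, rose while division genes fell. Of 41 measured, 34 rose and 0 fell, with a median of 0.83 (camera adjusted p = 1.65e-10; 0.0122 with an estimated correlation), against 0.13 for 9 variant histone genes. More cells in S phase is argued against by the S phase and mitosis list, whose median was -1.08. More RNA without a tail entering the label stays open: the 4 measured small nuclear, small nucleolar and ribosomal RNAs (Rnu6, Rn28s1, Snora65 and Snora70) had a median of 1.68, or 1.53 with Rn28s1, undetected in control, at its bound, but they were named after their values were seen, so this decides nothing. With RNA of 1 treatment on each set of arrays, such a difference in RNA cannot be separated from a change in how cells end histone messages, which was not tested, and near-identical histone copies are not independent measurements.

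The rise of Prf1, a gene of killer lymphocytes, was the largest of all. Its mean intensity went from 68.8 to 5172 at the used probe. Killer cells in the RI-BPI culture are argued against by their other genes: of 20 with a probe, 0 were detected on all 3 RI-BPI arrays without being detected on all 3 control arrays, and apart from Ccl5, which macrophages also express, the brightest mean was 53.1. A probe that reads another transcript may account for the signal, since the other probe named for Prf1 changed by 0.0093 near background. The positions of the probes are not given in the sources used here, so this and a rise of a Prf1 transcript in macrophages cannot be told apart.

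A rise of NF-kB and LPS-induced genes could come from more endotoxin in the RI-BPI preparation than in the control preparation. As the only difference this is argued against by the interferon response list, whose median was -0.607, since LPS raises those genes in macrophages. Ifnb1, which LPS also raises, was higher by 2.64 ± 0.11, so a contribution of endotoxin beside other effects of the peptide stays open. In the list of LPS-induced genes, 19 of 35 measured members rose, among them Cxcl1 (3.69) and Cxcl2 (2.61), and 6 fell. Of the others, Il1b, Acod1, Saa3, Ccl4, Cd14, Nos2 and Il10, named after their values were seen, were not called. Ccl5, also named then, was among those that fell (-0.32, limma adjusted p = 0.0137). Release of Bcl6 repression, the effect the peptide was built for, stays open too: the reported Bcl6 targets moved both ways and their camera p was 0.915, which decides nothing.

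The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 5031 genes and the highest of the others 0 (1 split of 10 reached the real count), for changes of at least 1.5-fold 2456 against 0 (1 of 10), and 9 lists against 8 (1 of 10). Every other split put arrays of both peptides in each group, so the peptide difference itself widened the spread within groups. Few gene calls there were fixed in advance, and the list counts there still hold part of the peptide difference. The splits therefore decide nothing about chance.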
